A study of Homo sapiens with 2 samples.

How the data were processed

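Poly(A) RNA from MCF-7 cells, an established estrogen receptor positive breast adenocarcinoma line, was profiled by RNA sequencing after transfection with small interfering RNA (siRNA) against estrogen receptor alpha (ERα, gene ESR1) or with a control siRNA. Per the labels' protocols, cells were kept in phenol red-free medium with 5% charcoal-treated serum for 3 days, a medium depleted of steroid hormones, and were transfected on day 2. The labels name 3 duplexes against ERα, without saying whether they were mixed, and the control was a commercial low-GC negative control duplex. The labels give 1 sample per condition, called siERα and siCTL here, and name no replicate. Libraries were made with an Illumina TruSeq RNA kit, per the labels' protocols, which do not state strand.

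Per the submitters' processing notes, TopHat2 2.0.6, HTSeq, edgeR and DESeq were used with the hg19 build; the notes as used here give these names without roles, order or settings. The data analysed are the authors' deposited table of 912 genes, with an Ensembl identifier, a symbol, a biotype, a p-value and a fold change for each. The p-value in the deposited table is named a Fisher combined p-value in its header; which p-values were combined, and whether they were adjusted for multiple tests, is not given in the sources used here. The log2 fold change in the deposited table is named an average in its header; what was averaged is likewise not given. The sign was read as siERα over siCTL because ESR1, the targeted gene, is negative. The rule by which genes entered the table is not stated. Every p-value in it lies at or below 0.00351, and 902 of its genes have an average change of at least 1.5-fold.

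The table holds no counts and no expression level per sample. The depth of each library is therefore unknown, no interval or standard error could be given, and no p-value was computed here across genes, which are not replicates. Tests planned for count data, the matching of random lists on expression level and the comparison of change with level were not run for the same reason. All p-values and fold changes quoted are the authors'. Of the p-values, 10 are written as 0 and a further 60 lie below 1e-300, near the smallest number a computer stores, so their order carries little information.

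From the table, genes were counted by direction, and 16 gene lists fixed before the data were examined were looked up by symbol or by Ensembl identifier: ER-induced, ER-repressed, luminal epithelial, basal and myoepithelial, mesenchymal, cell cycle, interferon response, p53 and apoptosis, stress response, growth factor signalling, neuronal, nuclear receptor and cofactor, sterol and lipid synthesis, housekeeping and RNA quality genes, and markers of stromal, endothelial and immune cells. A list member outside the table was counted as not listed, which says neither that it was unchanged nor that it was measured. For lists with at least 3 listed members, the median log2 fold change was placed among the medians of 10000 random lists of the same size from the rest of the table, as a description of these libraries. The number of members listed as higher was placed the same way; that statistic was added after the table was seen. Genes named in the text are ESR1, the 10 highest and 10 lowest fold changes, and up to 4 listed members per list with the smallest p-value. A minimum expression level of 100 normalised counts that the rule also asked for could not be applied. Genes named outside this rule were chosen after their values were seen, and the text says so.

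Gene positions, transcript GC content (all annotated transcripts of a gene pooled) and longest transcript length came from GENCODE release 44 lifted to GRCh37, the assembly behind hg19, matched by Ensembl identifier for 887 of 912 genes (97.3%). Random lists matched on GC content and length were drawn within strata formed by 3 equal groups of GC content and 3 of length. Computation used Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1. The list procedure was tested on simulated data for this comparison, with 400 lists of 20 genes drawn from the 912. Of lists made entirely higher, 92.8% lay above the middle 95% of random lists. Of lists with no planted direction, 6% fell outside the middle 95%. Lists made entirely lower and lists of other sizes were not simulated, so their rates are unknown. A rank correlation of -0.28 planted between GC content and fold change over 912 genes was recovered as -0.24.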

Results

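The comparison asked what ERα does in MCF-7 cells in the absence of added estrogen. Cells deprived of hormone for 3 days and transfected with siRNA against ERα (siERα, 1 sample) were set against cells transfected with a control siRNA (siCTL, 1 sample). The measurements were the average log2 fold change and the combined p-value per gene in the authors' deposited table, which holds 912 genes; the rule by which they entered it is not stated. The labels name no replicate and the table gives no spread between samples, so the values below carry no error, and the depth behind them is unknown.

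The direction of every value was set by ESR1, the targeted gene: the sign was read as siERα over siCTL because ESR1 is negative, so its own direction is no test of the knockdown. Its average log2 fold change in the authors' deposited table was -1.84, a 3.58-fold or 72.0% decrease, with a combined p written as 0. ESR1 (ENSG00000091831) is a protein-coding gene at chromosome 6, 151977826 to 152450754 on GRCh37. The authors' deposited table listed 912 genes, of which 408 (44.7%) were higher and 504 (55.3%) lower in siERα. The median log2 fold change in the authors' deposited table was 1.15 among higher genes and -1.15 among lower genes. At least a 2-fold change was given in the authors' deposited table for 255 higher and 309 lower genes, and at least a 4-fold change for 71 and 108.

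**Figure D1:**
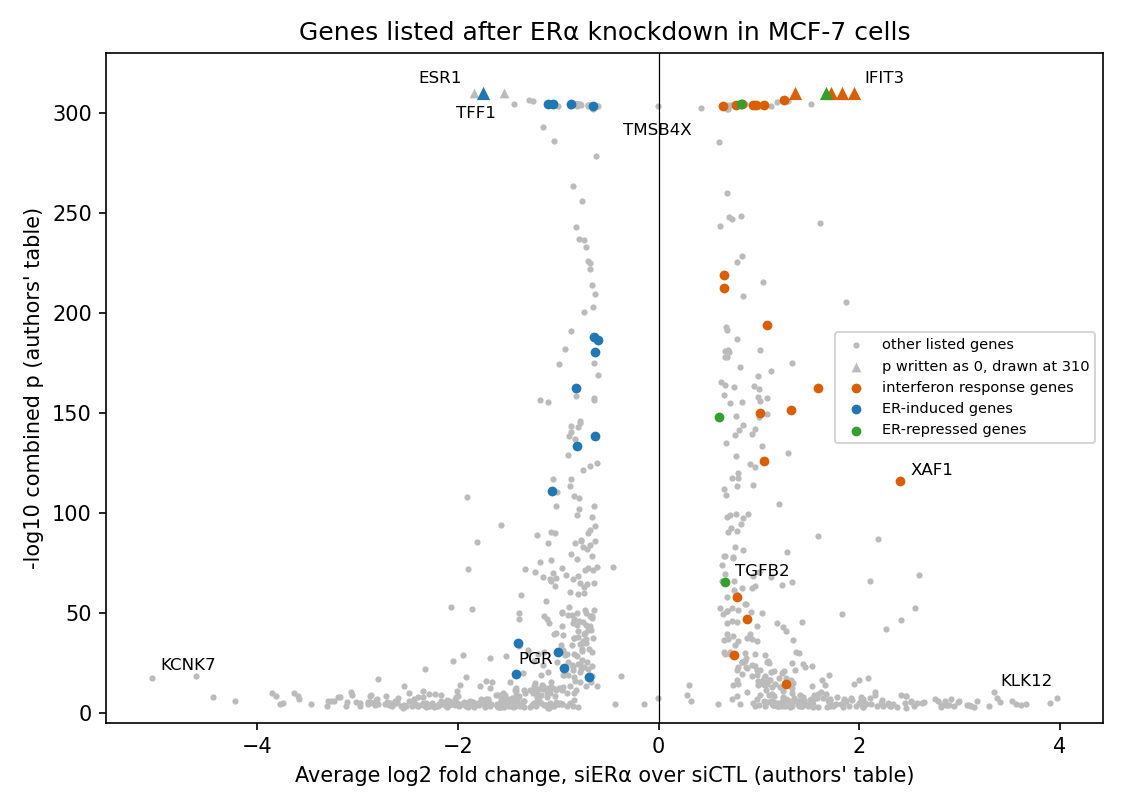
Each point is 1 of the 912 listed genes, with the average log2 fold change of siERα over siCTL on the x axis and the -log10 of the combined p on the y axis, both from the authors' deposited table; triangles are genes whose p is written as 0, drawn at a fixed height, and colours mark 3 gene lists. ESR1 and TFF1 lie on the lower side and IFIT3 on the higher side at the top, while the extreme fold changes (KCNK7 at -5.05, KLK12 at 3.97) lie near the bottom.

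All listed members of the list of known estrogen-induced genes of MCF-7 cells were lower, in the same direction as ESR1. Of 46 such genes on a list fixed beforehand, 17 were in the authors' deposited table, with 0 higher, 17 lower and a median log2 fold change of -0.87. TFF1 (chromosome 21, 43782391 to 43786644), a secreted trefoil peptide and classical ERα target, had a log2 fold change of -1.75 in the authors' deposited table, close in size to ESR1. STC2, a secreted stanniocalcin, was at -1.10 in the authors' deposited table, XBP1, a transcription factor of the unfolded protein response, at -1.05, and AGR2, a protein disulfide isomerase, at -0.87. Their combined p-values in the authors' deposited table were 0 as written for TFF1, 2.33e-305 for STC2, 2.5e-305 for XBP1 and 2.95e-305 for AGR2. Random lists of 17 genes from the same table held 8 higher genes at the median (4 to 12 in the middle 95%), and 0.01% of them held none. The list's median lay at percentile 14.7 of the medians of those random lists, which mix higher and lower genes, so that percentile does not measure size. By size, the list's median of -0.87 was smaller than the median of -1.15 among all lower genes of the authors' deposited table. Those genes take in all biotypes and p-values. In size the list's median also lay below the median absolute change of 1.04 among protein-coding genes. It lay above that of 0.82 in the 183 genes with the smallest p-values. The other 29 members, among them GREB1, MYC, CCND1 and NRIP1, were not listed.

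The listed members of the list of genes that estrogen represses in these cells were higher. Of 13 on the list, 4 were in the authors' deposited table and 4 were higher, with a median of 0.74. TP53INP1, a p53-inducible nuclear protein, was at 1.67 in the authors' deposited table, the pro-apoptotic BCL2 family member BMF at 0.82, the cytokine ligand gene TGFB2 at 0.66 and the interleukin receptor gene IL1R1 at 0.61. As many as 3.99% of random lists of 4 genes were all higher, and the list's median lay at percentile 78.7 of theirs. All 4 higher is the most one-sided outcome that a list of 4 can give. The direction count therefore cannot decide whether so short a list stands apart from the rest of the table. The median cannot decide it either. The middle 95% of random list medians ran from -1.82 to 1.52. The median of 1.15 among all higher genes lies inside that range. An entirely higher list of ordinary size can therefore stay inside, as this list did.

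All listed members of the list of interferon-stimulated genes were higher, and this list had the most members in the table. Of 31 on the list, 23 were in the authors' deposited table, 23 higher and 0 lower, with a median log2 fold change of 1.05 and a range from 0.65 to 2.41. IFIT3 (chromosome 10, 91087064 to 91137230), an antiviral tetratricopeptide protein, was at 1.95 in the authors' deposited table, OAS2, an oligoadenylate synthetase activated by double-stranded RNA, at 1.83, IFIT1 at 1.72 and IFI27 at 1.36. These 4 genes have a combined p written as 0 in the authors' deposited table. The cytosolic sensors of double-stranded RNA were also members, with DDX58 (RIG-I) at 1.05 and IFIH1 (MDA5) at 1.01 in the authors' deposited table; both, and XAF1 at 2.41 as the list's maximum, were named after their values were seen. None of 10000 random lists of 23 genes was entirely higher (median 10 higher, middle 95% from 5 to 15), and the list's median lay at percentile 99.5. That percentile does not measure size, since random lists mix higher and lower genes. The list's median of 1.05 lay below the median of 1.15 among all higher genes of the authors' deposited table. Those genes take in all biotypes and p-values. The median absolute change was 1.04 among protein-coding genes and 0.82 in the 183 genes with the smallest p-values. How large the list's change appears thus depends on the genes it is set against. The other 8 members were not listed.

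**Figure D2:**
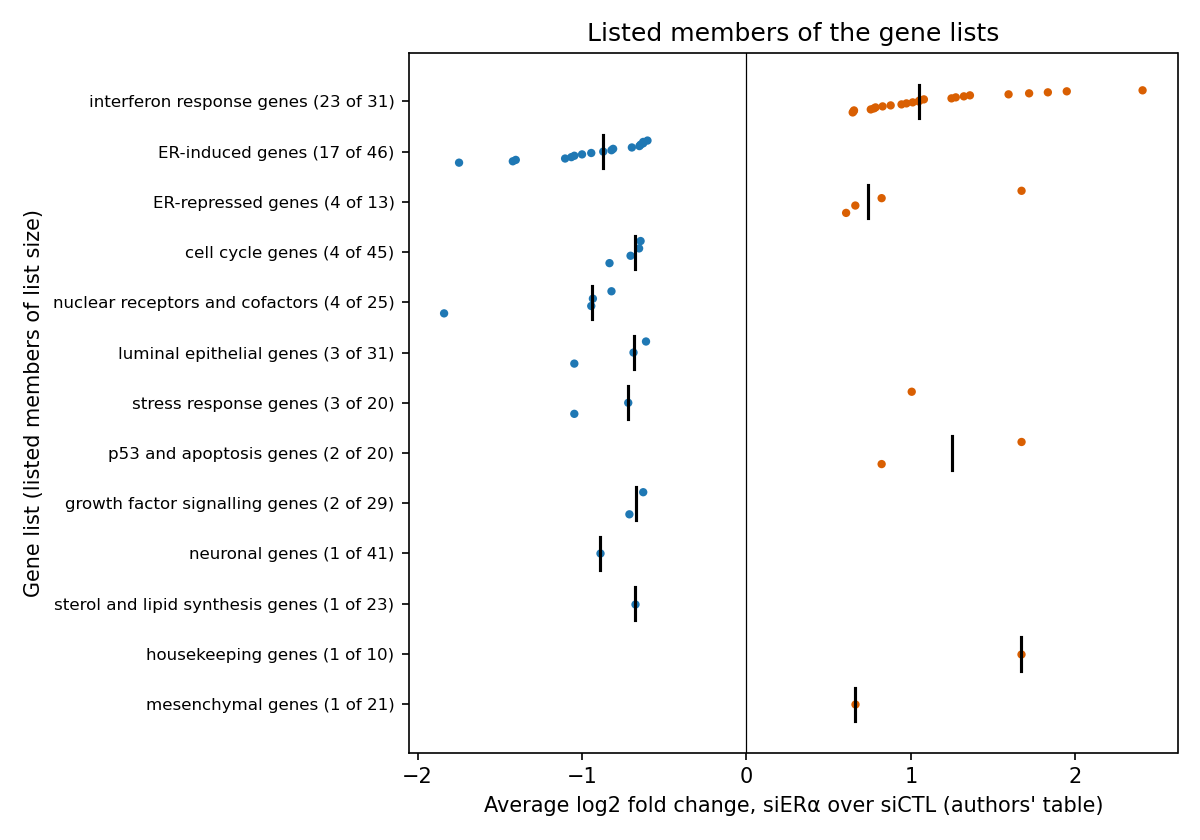
Points are the listed members of each gene list, with their average log2 fold change (siERα over siCTL, authors' deposited table) on the x axis; orange is higher, blue is lower, black bars are list medians, and the numbers in brackets give listed members and list size. The 23 interferon response genes all lie above 0 and the 17 ER-induced genes all lie below 0.

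The receptor genes PGR, VDR and RARA were listed as lower beside ESR1. Of 25 nuclear receptors and cofactors, 4 were in the authors' deposited table and all 4 were lower, with a median of -0.94, but 1 of them is the targeted gene. The progesterone receptor gene PGR was at -0.94 in the authors' deposited table (combined p 8.05e-23), the vitamin D receptor gene VDR at -0.93 (1.9e-182) and the retinoic acid receptor gene RARA at -0.82 (2.38e-163). PGR and RARA also belong to the ER-induced list. As many as 8.91% of random lists of 4 genes were as one-sided, and the list's median lay at percentile 25.1. No list of 4 can be more one-sided, so the direction count cannot decide whether this list stands apart from the rest of the table. The median cannot decide it either. The middle 95% of random list medians ran from -1.85 to 1.57. The median of -1.15 among all lower genes lies inside that range. An entirely lower list of ordinary size can therefore stay inside, as this list did. The other 21 members, among them AR, ESR2, NR3C1 and RARB, were not listed.

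Most genes of the proliferation and breast lineage lists were not in the table. It held 727 protein-coding genes where 20175 are annotated, so these counts do not show a shortage. Of 45 cell cycle genes, 4 were in the authors' deposited table, all lower, with MYBL2, a transcription factor of cycling cells, at -0.65, the anaphase activator CDC20 at -0.71, E2F1, a transcription factor of the G1 to S transition, at -0.83 and the topoisomerase TOP2A at -0.64. Their median of -0.68 lay at percentile 38.1 of random lists, and 9.39% of random lists of 4 genes were as one-sided. Of 31 luminal epithelial genes, 3 were in the authors' deposited table and were lower: XBP1, the keratin gene KRT19 at -0.61 and the cadherin family gene CELSR1 at -0.69. That list's median lay at percentile 48.9, with 16.2% of random lists of 3 genes as one-sided, and the luminal transcription factor genes GATA3 and FOXA1 were not listed. None of 33 basal and myoepithelial genes and none of 15 stromal, endothelial and immune markers was listed, and 1 of 21 mesenchymal genes was (TGFB2).

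The remaining lists had 3 members or fewer in the table. Of 20 stress response genes, XBP1 and the heme oxygenase gene HMOX1 (-0.72) were lower and the lipoprotein receptor gene VLDLR (1.01) was higher in the authors' deposited table, with the list's median at percentile 45.9. Of 20 p53 and apoptosis genes, TP53INP1 and BMF were listed, and both are also ER-repressed genes. Of 29 growth factor signalling genes, the authors' deposited table held IGFBP4, which encodes a binding protein of insulin-like growth factors, at -0.63 and PDGFB, a platelet-derived growth factor gene, at -0.71. Of 23 sterol and lipid synthesis genes it held the fatty acid synthase gene FASN, at -0.68 (combined p 1.87e-304) in the authors' deposited table, and of 41 neuronal genes the semaphorin gene SEMA3B, at -0.89. Of 10 housekeeping genes, only B2M was in the authors' deposited table, at 1.67; it encodes the light chain of MHC class I and is itself interferon-inducible. None of 16 RNA quality genes was listed.

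Genes that are not protein-coding made up 8 of the 10 highest and 4 of the 10 lowest fold changes. The 10 highest log2 fold changes in the authors' deposited table ran from 3.29 to 3.97 and included 2 protein-coding genes, the kallikrein gene KLK12 at 3.97 and the mitochondrial ornithine carrier gene SLC25A2 at 3.40. The other 8 were the pseudogenes SKP1P1 (3.53), AC104600.1 (3.37) and RP11-128A6.2 (3.34), the lincRNAs CTD-2023M8.1 (3.66) and CTC-498J12.1 (3.56), the antisense genes RP3-327A19.5 (3.90) and CTD-2530H12.4 (3.62), and the small nuclear RNA RNU4-2 (3.29), all from the authors' deposited table. The 10 lowest in the authors' deposited table included 6 protein-coding genes: the potassium channel gene KCNK7 (-5.05), C9orf24 (-4.22), the cyclic nucleotide-gated channel gene CNGA4 (-3.85), CYP19A1 (-3.81), which encodes the estrogen-synthesising aromatase, the receptor gene GPR3 (-3.64) and the sulfotransferase gene HS3ST6 (-3.60). The pseudogenes AC090945.1 (-4.61) and RP11-1379J22.3 (-3.77), the processed transcript RP11-223A3.1 (-4.44) and the lincRNA RP11-47P18.1 (-3.74) made up the rest of the 10 in the authors' deposited table. Across the authors' deposited table, 39.5% of 185 genes that are not protein-coding changed at least 4-fold, against 14.6% of 727 protein-coding genes. Their median combined p in the authors' deposited table was 1.19e-05, against 3.42e-30 for protein-coding genes. Pseudogenes share sequence with their parent genes and antisense genes share positions with partners, so these values are uncertain. Across all biotypes, the median absolute log2 fold change was 0.82 in the 183 genes with the smallest p-values and 1.77 in the 183 with the largest. Without counts, whether the extreme changes rest on few reads is unknown, for protein-coding genes as well.

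The direction of change followed the base composition of the transcripts. Among 717 protein-coding genes of the authors' deposited table with annotated transcripts, the median GC content was 44.8% for the 332 higher genes and 58.3% for the 385 lower genes. All 20175 annotated protein-coding genes have a median of 49.5%. When these listed genes were ranked by GC content and divided into 5 equal groups, 84.7% were higher in the group with the lowest GC content and 6.25% in the group with the highest. Spearman's rho across these genes, which are not independent replicates, was -0.47 between log2 fold change and GC content. The listed ER-induced genes had a median GC content of 57.1% and the listed interferon response genes 47.1%. Among random lists matched on GC content and length, 3 of 10000 held no higher gene, as the ER-induced list did, and 0 of 10000 were all higher, as the interferon response list was.

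**Figure D3:**
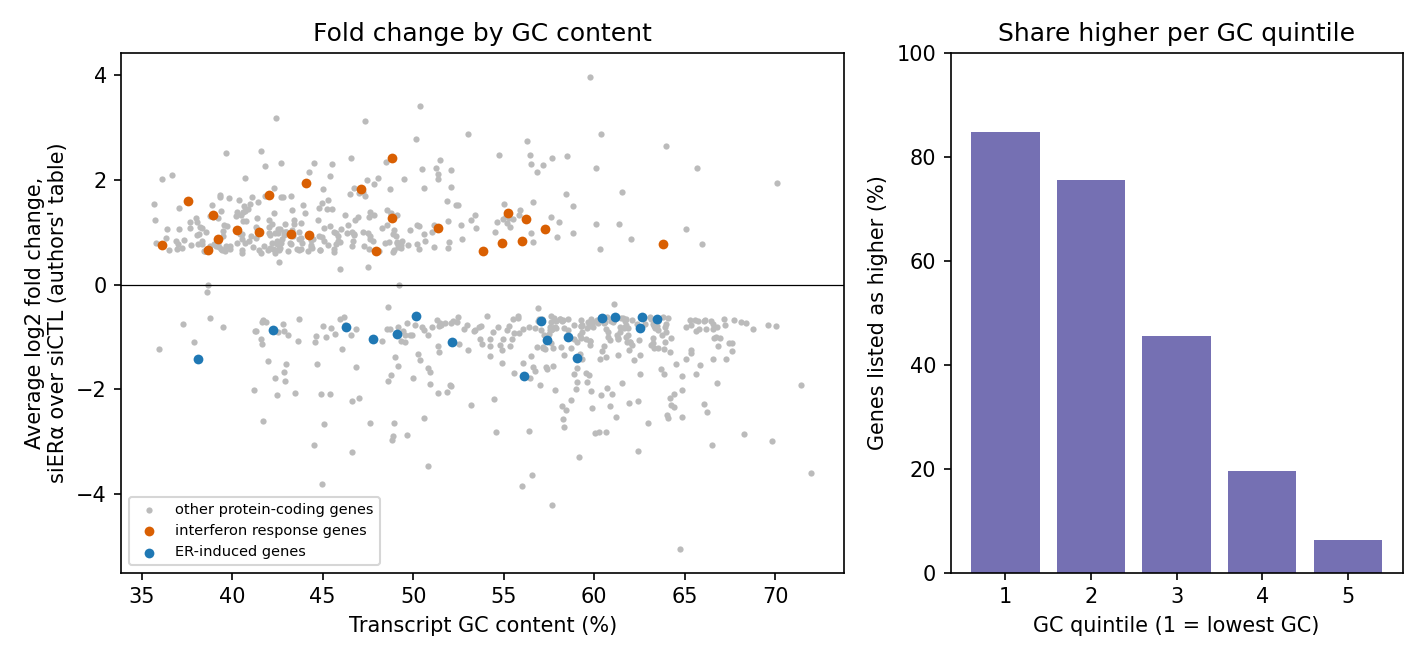
Left, each point is a listed protein-coding gene, with the GC content of its annotated transcripts (%) on the x axis and its average log2 fold change (siERα over siCTL, authors' deposited table) on the y axis. Right, bars give the percentage of listed protein-coding genes that are higher in each of 5 equal groups by GC content, falling from 84.7% in the lowest to 6.25% in the highest.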

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

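Depth and replicate spread are unknown here, so these alternatives test only how genes were picked from the authors' deposited table. A minimum of 1 on the absolute log2 fold change, planned beforehand, took the counts from 408 higher and 504 lower genes to 255 and 309. A combined p under 0.01 and 1 row per gene symbol removed no gene, because every listed p is smaller and no symbol recurs, so neither tests anything. The settings chosen after seeing the data were protein-coding genes only, leaving out the 10 genes with an average change under 1.5-fold, leaving out the interferon response list, a combined p under 1e-05, random lists matched on GC content and length, and the number of higher members of a list. Under the first 4 the higher genes numbered 339, 404, 385 and 319 in that order, and the lower genes 388, 498, 504 and 376. Centring on the table's median moved list medians to -0.19 for ER-induced, 1.42 for ER-repressed, -0.01 for luminal epithelial, -0.002 for cell cycle, 1.72 for interferon response and -0.26 for nuclear receptor genes. The list of stress response genes moved to -0.042. The table's 2 clusters of values, with more genes lower than higher, place that median inside the lower cluster, so the shift follows from the construction, and none of these 7 medians changed sign; lists with fewer than 3 listed members were not centred, and among them the growth factor signalling (-0.67) and sterol and lipid synthesis (-0.675) lists lie just above the table's median of -0.677 and would change sign. Matching random lists on GC content and length left the interferon response list at percentile 98.95 and the ER-induced list at percentile 27.37, and no fixed list with a percentile moved into or out of the middle 95%. No paired analysis was possible because the labels give 1 sample per condition. Leaving out replicates, other count normalisations, low-count filters, matching on expression level, a pseudocount and the comparison of change with level were not run, since the table holds neither counts nor levels; for ESR1 only the deposited value was used.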

Other observations

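Tests by direction of list members, the interferon ligand count and the gene groups in the first 2 paragraphs were chosen after their values were seen. Matching on GC content and length was added after the table was seen, and the bounds of the remaining tests were set before their results. Of 35 genes of antigen processing and presentation, a list drawn up after the table was seen, 10 were in the authors' deposited table, 10 higher and 0 lower, with a median log2 fold change of 1.26, and 25 were not listed. They included the class II genes HLA-DPA1 (2.42) and HLA-DRA (2.00), the class II invariant chain gene CD74 (2.42), the class I light chain gene B2M (1.67), the class I transactivator gene NLRC5 (1.29), the immunoproteasome genes PSMB8 (1.23) and PSMB9 (1.12), the peptide transporter genes TAP2 (1.04) and TAP1 (0.83) and the trimming peptidase gene ERAP1 (1.01) in the authors' deposited table. Its median lay at percentile 99.1 of random lists, which is a description and no test, since the list was chosen after the values were seen. None of these genes is on the interferon response list, but B2M is itself interferon-inducible, so absence from that list does not make them a separate pattern. PSMB9 overlaps both PSMB8 and TAP1 on chromosome 6, so their values are not independent.

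Some gene families in the table had all listed members on 1 side. The mucin genes MUC5B (-1.74), MUC16 (-1.68), MUC6 (-2.26) and MUC2 (-1.87) were lower in the authors' deposited table, with a median at percentile 2.86 of random lists, inside their middle 95%, and at percentile 1.06 of lists matched on GC content and length. Other families were mixed. Of 8 zinc finger genes of the ZNF series, 7 were higher and 1 lower, with a median of 1.44 at percentile 99.5 of random lists and 99.6 of matched lists. Lower were 6 of 7 KCN potassium channel genes (percentiles 16.5 and 39.9) and 5 of 7 GPR receptor genes (5.33 and 2.26). So were 19 of 28 solute carrier genes (11.1 and 7.89) and 4 of 6 ribosomal protein genes (42.0 and 55.5). All 7 clustered protocadherin genes in the authors' deposited table were lower, with a median of -1.07 at percentile 13.6 of random lists and 1.83 of matched lists, but the 6 alpha genes among them share exons and are not independent. The medians of other one-sided families lay inside the middle 95% of random and of matched lists. All 5 PARP genes were higher (percentiles 85.5 and 80.85), as were all 3 APOL genes (94.1 and 90.98). All 3 serpin A genes (24.5 and 32.56) and all 4 synaptotagmin genes (32.3 and 62.19) were lower. Families this short can lie entirely on 1 side and still stay inside. Other lower genes in the authors' deposited table were the telomerase gene TERT (-2.34), the imprinted noncoding RNA gene H19 (-1.81) and the calcitonin receptor gene CALCR (-2.07). These families were picked from the table, and their percentiles are descriptions. Of 17 genes with interferon in their description, 14 were higher and 3 lower in the authors' deposited table, the lower ones being IFITM10 (-1.15), IFI27L2 (-0.84) and the pseudogene IFNA20P (-3.12). Of 44 pairs of listed genes that overlap on the genome, 42 changed in the same direction, including 21 of 21 pairs on opposite strands, against 50.6% from the table's split of directions. These pairs are not independent, since 15 are pairings of the 6 alpha protocadherin genes and 5 come from the PSMB8, PSMB9 and TAP1 locus; outside both, 22 of 24 pairs changed in the same direction, including 17 of 17 on opposite strands. Without stated strand, reads of such partners cannot be separated.

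The first pattern is the split of directions by GC content. Spearman's rho between log2 fold change and GC content was -0.41 across the 829 genes outside the fixed lists, but these are most of the genes that show the split, so this restates it and decides nothing about its cause. Between log2 fold change and transcript length, rho was 0.14 over all listed genes. Within the 3 GC groups it was -0.095 in the lowest, 0.13 in the middle and 0.11 in the highest. The change of sign argues against a length trend that holds at every GC content, but a weak one above the lowest group stays open. The rho with GC content was -0.47 in protein-coding genes and -0.28 in the 170 genes of other biotypes, and whether these differ was not tested. A difference in GC response between libraries and an effect of knockdown on genes of differing composition cannot be told apart, so both stay open. The labels give 1 sample per condition, and the data hold no counts.

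The second pattern is the one-sided direction of the interferon response and ER-induced lists. Few lists matched on GC content and length were so one-sided: 0% for the interferon response list and 0.03% for the ER-induced list. This argues against the GC and length trend as the source of either direction, but the count was chosen after its values were seen. The matching was also coarse. Within GC groups, rho of log2 fold change with GC content was still -0.078 (lowest), -0.15 (middle) and -0.051 (highest). A remaining part of the trend is therefore not excluded. The interferon list's median at percentile 98.95 of matched lists is no separate evidence, because a list entirely of higher genes reaches a high percentile by direction alone. The ER-induced list's median lay at percentile 27.37 of matched lists, whose middle 95% ran from -1.19 to 0.66. The median of -1.15 among all lower genes of the table also lies inside that range. An entirely lower list of ordinary size can therefore stay inside, so the median cannot decide about the trend for this list. Whether interferon genes rose because ERα was lost or because cells answered the transfected duplexes cannot be told apart: 1 interferon ligand gene, IL28A (IFNL2) at 1.31 in the authors' deposited table, was higher, which either could give, and only 1 sample has ERα lowered, by duplexes other than the control duplex.

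The third pattern is a set of 10 genes with an average change under 1.5-fold beside small p-values, while the next smallest change is 0.59. TMSB4X had a log2 fold change of -0.008 with a combined p of 2.33e-304 and AIMP1 -0.007 with 5.47e-08 in the authors' deposited table; the others were RCN1, SUFU, CDC42EP2, RPL17, AC073869.1, FBXW10, CBWD5 and CASP14. Of these 10 genes, 4 have an annotated pseudogene named after them, against a median of 1 and a middle 95% of 0 to 2 in random lists. Reads shared with pseudogene copies may therefore contribute. The count goes by name and takes in pseudogenes of any kind, and it does not say how so small a p arises beside so small a change. As for reads shared with an overlapping gene, 7 of the 10 overlap another gene, equal to the median of random lists. That count cannot decide, since the middle 95% of those lists ran from 4 to 9. Overlap was also counted over whole gene spans. An average of values with opposite signs would also give such rows, and the values that were averaged were not analysed here.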
